A study of Mus musculus with 21 samples.

How the data were processed

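Spleen homogenates of 21 female mice were profiled, 3 mice in each of 7 groups. A/J mice were sampled uninfected and 3, 5 and 7 days after infection with 1000 CFU of *Salmonella* Typhimurium strain Keller, and AcB60 mice uninfected and at days 3 and 7. AcB60 is a recombinant congenic strain bred from A/J and C57BL/6J mice. The labels describe total RNA taken with TriZol and RNeasy columns and biotinylated cRNA made with an Ambion MessageAmp kit for Illumina bead arrays. Replicate numbers name the mice of a group.

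The deposited table held 1 mean bead intensity per probe and array, which the authors had not normalized between arrays. Next to each intensity stood, per the file headers, a detection p-value for that probe and array. A deposited table of processed values held the same intensities in all 539637 cells, so it was no separate normalization. On 1 array the detection p-value broke its order with intensity at 1 probe. The submitters' processing notes name lumi with no version given, and neither the background treatment nor slides or batches are stated.

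Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16, and taken to log2. Of 25697 probes, 14354 had a detection p-value under 0.05 on at least 3 arrays and were kept. Gene symbols came from the platform annotation, which gave 23978 probes 1 symbol and 1719 probes none. For each gene the probe with the highest mean was tested, which left 10953 features, of which 10109 were named genes and 844 probes without a symbol. Gene order along the chromosomes came from the mouse reference annotation and was used only to count neighbouring genes.

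A linear model with a mean for each of the 7 groups was fitted to all 21 arrays with limma, so that all groups shared 1 estimate of the spread. Of 13 contrasts, 5 compared infected with uninfected mice of a strain, 2 compared day 7 with day 3, 4 compared the strains (uninfected, day 3, day 7 and the mean of these conditions) and 2 tested the strain by infection interaction. Moderated statistics from eBayes were adjusted with the Benjamini-Hochberg method within each contrast, and an adjusted p under 0.05 counted as past the test. All tests are two-sided except the permutations of gene order, with 100000 resamples, and of replicate numbers, which are one-sided. Values are log2 changes ± the standard error from limma with n = 3 mice per group, or 9 mice per strain for the averaged contrast. All p-values printed for genes are limma's adjusted p.

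The lists cover interferon-inducible GTPases, type I interferon-stimulated genes, MHC class I and antigen processing, MHC class II, inflammatory cytokines, chemokines, neutrophil markers, inflammatory monocyte markers, phagocyte antimicrobial effectors, red pulp and marginal zone macrophage markers, pattern recognition and inflammasome, complement and acute phase, B cell markers, plasma cell markers, T cell markers, NK and cytotoxic lymphocyte markers, dendritic cell markers, erythroid and haem synthesis, megakaryocyte and platelet markers, mitosis and DNA replication, iron handling, glycolysis, stromal, matrix and endothelial markers, pancreatic acinar markers and adipose markers. These 25 lists, the samples, the contrasts, the tests, the rule for named genes and the settings below, except the left-out sets of arrays chosen for their measured values, were chosen before the data were examined. Each list was tested with camera of limma against all other named genes, with a preset correlation between genes of 0.01, and adjusted over all 325 tests. Members past the test were counted over all genes and also adjusted over the list alone. Camera with a correlation estimated for each list and fry were run as alternatives.

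Genes to name were taken by rule. For infected against uninfected mice they were the 10 most positive and 10 most negative changes past the test in which all 3 mice of a group lay on the same side of all 3 mice of the other. The averaged strain contrast used the same numbers with that separation in each of its 3 conditions, and the remaining contrasts used 5 and 5. Clone names, predicted genes and immunoglobulin or T cell receptor segments were left out. Up to 4 members past the test came from each list described, and members not past the test are given by their values only. Where the tested probe was detected on no array of a group, the fold change is a lower bound against the lowest detected signal of each array and is written "at least N-fold".

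The quality of each array was read from 1060 genes with 2 bright probes, with a mean above 7 on the log2 scale. For each array the share of these pairs whose difference lay over 1 log2 unit from its median over the arrays was counted. The fit was tested on simulated data in which 200 genes were altered by 1, 2 or 3 log2 units. Changes of 2 units were recovered for 79.1% of such genes at A/J day 7, 98.5% in the averaged strain contrast and 40.3% in the interaction at day 7. Of the simulated calls, 2.99%, 6.77% and 6.17% were false. The simulated noise was independent between genes and had the same spread on all arrays. Estimated weights of the measured arrays ran from 0.154 to 3.07, so these rates need not hold for the measured data.

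Other settings tried were median centring, quantile normalization without background correction, no detection filter, a stricter filter, all probes, array weights, a minimum change of 1 log2 unit, only the arrays compared, a replicate block, the age-matched AcB60 mouse and each array left out in turn. Leaving out arrays chosen for their measured values was added after the data were seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. No array was left out of the reported fit.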

Results

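Gene expression was measured in spleen homogenates of A/J and AcB60 mice, uninfected or infected with 1000 CFU of *Salmonella* Typhimurium strain Keller, with 3 female mice in each of 7 groups. A/J spleens were taken uninfected and at days 3, 5 and 7, and AcB60 spleens uninfected and at days 3 and 7. Mean raw intensity per array ranged from 362 to 1140, and 10128 to 12359 probes were detected per array. The number of arrays limits the precision. The A/J mice were 13 weeks old and the AcB60 mice 16 weeks, except AcB60 day 3 replicate 1 at 13 weeks, so age and strain were almost fully confounded. Changes are log2 values ± standard error with 3 mice per group, and p-values are adjusted p from limma for genes and from limma's camera for lists. By the rule for naming, every gene named for the size of its rise or fall after infection separated all 3 infected from all 3 uninfected mice. Of 325 list tests, 153 passed with the preset correlation and 8 with an estimated correlation. The 8 were the neutrophil and the megakaryocyte lists between the strains (uninfected, at day 3 and averaged), the B cell list in the averaged strain contrast and the phagocyte effector list in AcB60 at day 7.

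Several arrays stood apart from their groups. On A/J day 7 replicate 1, 47.0% of 1060 probe pairs of the same gene lay over 1 log2 unit from their usual difference, followed by A/J day 5 replicate 1 with 29.6% and A/J day 7 replicate 2 with 15.6%. The other 18 arrays lay between 1.60% and 11.04%. Transcripts of pancreatic acinar cells had a list mean of 10.4 on A/J day 3 replicate 3 and 9.52 on A/J day 7 replicate 2, against 6.61 on AcB60 day 7 replicate 2 and at most 6.22 elsewhere. AcB60 day 3 replicate 3 had a mean of 8.003 over the interferon-inducible GTPases, where the other two mice of its group had 10.1 each. AcB60 uninfected replicate 3 correlated across genes at 0.980 with the mean of uninfected A/J mice and at 0.960 with the mean of the other two mice of its group, and 11 of 21 arrays correlated most closely with the mean of another group. On a scale over the genes that differ between the strains, from −1 at the A/J mean to 1 at the AcB60 mean, it stood at 0.769, with the AcB60 arrays between 0.392 and 1.39 and the A/J arrays between −1.41 and −0.489.

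**Figure D1:**
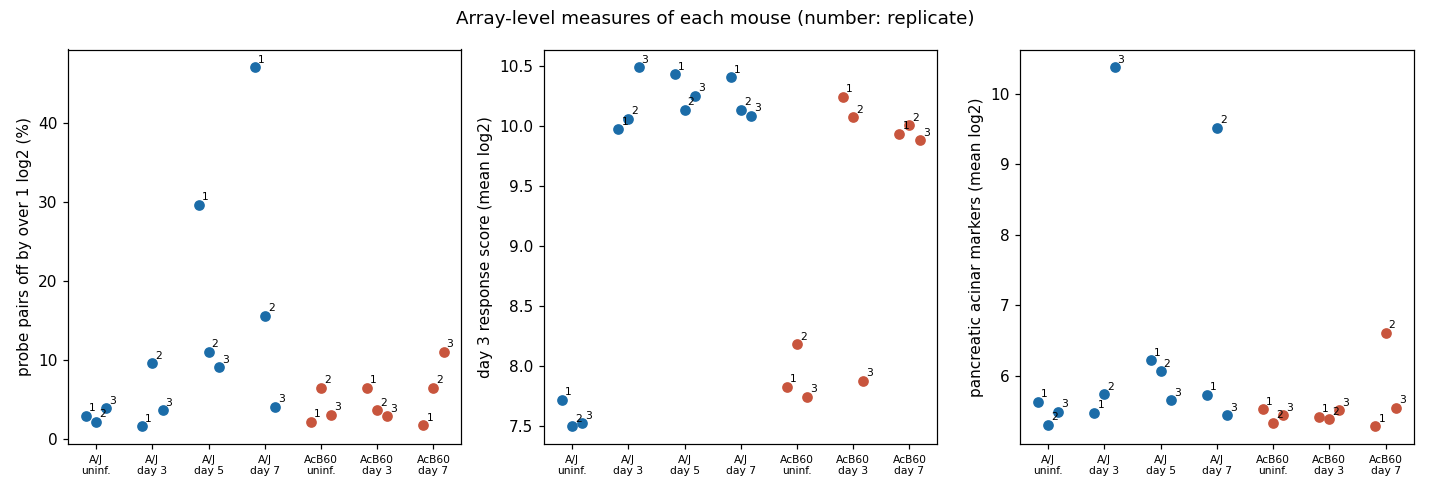
Per-array measures, with the percentage of probe pairs over 1 log2 unit off, the mean log2 level of 35 infection-responsive genes and the mean log2 level of acinar markers on the vertical axes, and 1 point per array grouped by strain and day. A/J day 7 replicate 1 stands at 47.0% of pairs, AcB60 day 3 replicate 3 at a response level of 7.88 beside uninfected AcB60 mice at 7.74 to 8.18, and A/J day 3 replicate 3 at an acinar mean of 10.4.

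The first comparison asks what had changed in the A/J spleen by day 3 of infection. Ifng, the cytokine interferon gamma, rose by 4.66 ± 0.94 (adjusted p = 0.0417) and was detected in only 2 of 3 uninfected mice. The neutrophil-attracting chemokine Cxcl1 rose by 4.56 ± 0.74 (adjusted p = 0.0110), with detection in 1 of 3 uninfected mice. The antiviral RNA-sensing enzyme Oas2 rose by 4.19 ± 0.66 and the guanylate-binding protein Gbp2, a GTPase that acts on intracellular pathogens, by 4.04 ± 0.77. Timp1, an inhibitor of matrix metalloproteinases, rose by 3.57 ± 0.71. Of the 4 genes that fell, Cxcl13, the chemokine that draws B cells into follicles, fell by 1.85 ± 0.38 (adjusted p = 0.0417). Cbr2, a carbonyl reductase detected in 2 of 3 day 3 mice, fell by 1.59, while Rnf220 was at least 1.70-fold lower and Itm2a at least 1.52-fold lower.

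By list, 3 of 13 interferon-inducible GTPases rose (median change 2.10, adjusted p = 6.89e-17), and 12 rose when adjusted over the list alone. Gbp5 was at least 7.74-fold higher and Igtp rose by 2.10 ± 0.35. The list's adjusted p = 0.0512 with an estimated correlation. Of 25 type I interferon-stimulated genes 8 rose and 15 did when adjusted over the list alone (median 1.39, adjusted p = 1.23e-18), among them the transcription factor Irf7 at 3.14, Mx2 at 2.98, Oasl2 at 2.90 and Oasl1 at 2.85. That list had adjusted p = 0.0599 with an estimated correlation. Inflammatory cytokines rose as a list (median 0.62, adjusted p = 1.19e-08, and adjusted p = 0.128 with an estimated correlation), with 2 of 20 members past the test, Ifng and Osm. Pattern recognition genes rose as a list with 0 of 25 members past limma's test over all genes and 10 when adjusted over the list alone (median 0.76, adjusted p = 1.07e-08, and adjusted p = 0.169 with an estimated correlation). The MHC class I list also rose (median 0.70, adjusted p = 7.60e-06, and adjusted p = 0.189 with an estimated correlation), with its regulator Nlrc5 up by 2.25 ± 0.39.

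B cell markers fell as a list by a median of 0.52 (adjusted p = 2.53e-05, and adjusted p = 0.211 with an estimated correlation) and the erythroid list by a median of 1.00 (adjusted p = 3.79e-07, and adjusted p = 0.375 with an estimated correlation). No erythroid member passed limma's test, and Hemgn had −2.09 ± 0.92 and Hbb-bt −1.68 ± 0.72. Without A/J day 3 replicate 3 the erythroid median was −0.46 and Hemgn had −1.05. The pancreatic acinar list was higher (median 1.87, adjusted p = 6.50e-05, and adjusted p = 0.458 with an estimated correlation) with 0 of 14 members past limma's test. Its members Pnliprp1 and Cela2a, enzymes of pancreatic juice, had 12.41 and 12.90 in A/J day 3 replicate 3 and between 4.72 and 5.10 in the other two mice. Without that mouse the acinar list had adjusted p = 0.686 and mitosis and DNA replication, lower at the full sample size (median −0.51, adjusted p = 0.00424, and adjusted p = 0.591 with an estimated correlation), had adjusted p = 0.239.

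In all, 35 genes were higher and 4 lower at day 3 in A/J, with 1239 at an unadjusted p under 0.05. The count fell to 0 without A/J day 3 replicate 2, A/J day 3 replicate 3, A/J uninfected replicate 2 or A/J uninfected replicate 3, and to 7 without A/J uninfected replicate 1. None of the named genes kept its call with each of the 6 arrays left out. The interferon, cytokine and B cell lists kept their call with every array left out in turn. Median centring gave 12 higher and 0 lower and shifted the median of all genes to 0.15. Arrays of other groups, when left out, could change the count only through the spread shared by all groups. The total of 39 became 20 without a detection filter and 0 without the 2 arrays with acinar transcripts. It became 823 with array weights, 367 with only the arrays compared, 101 without the 2 arrays with disagreeing probes (A/J day 5 replicate 1 and A/J day 7 replicate 1), 196 without AcB60 day 3 replicate 3 and 438 without these 3 arrays and A/J day 7 replicate 2.

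**Figure D2:**
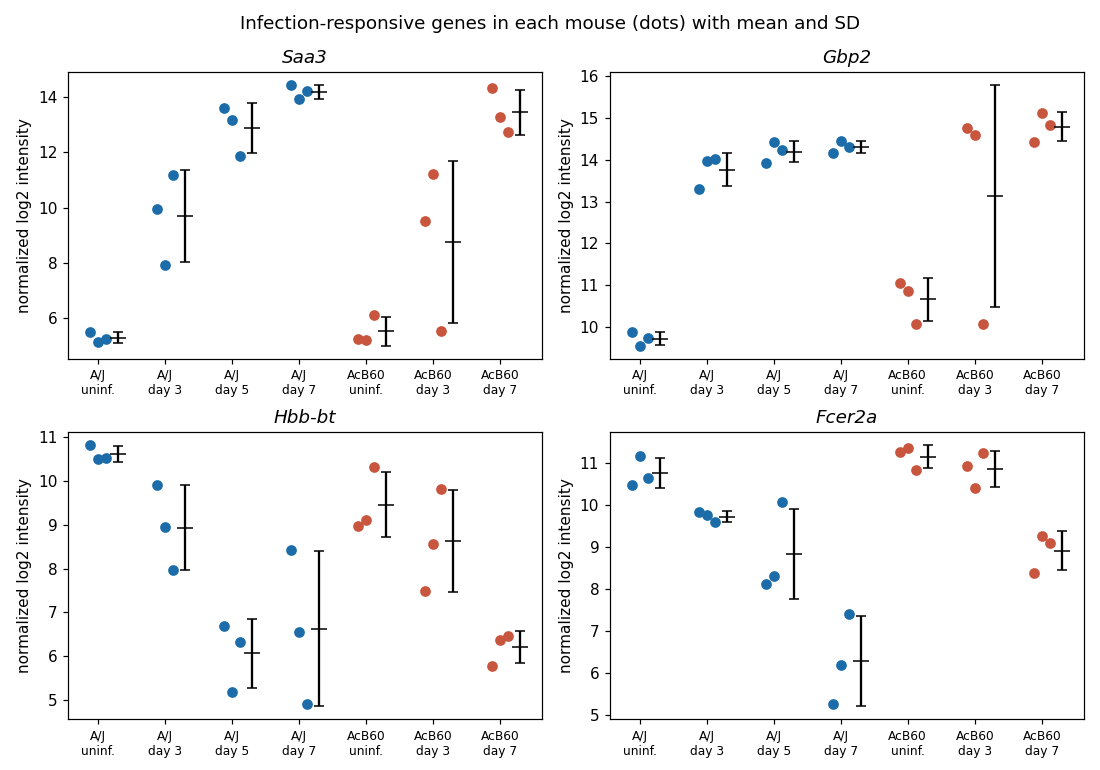
Normalized log2 expression on the vertical axis for Saa3, Gbp2, Hbb-bt and Fcer2a in each of the 7 groups, with 1 dot per mouse and the mean ± SD of 3 mice. Saa3 stood at 5.14 to 5.52 in uninfected A/J mice and 13.93 to 14.42 at day 7, while Fcer2a went from 10.48 to 11.18 down to 5.25 to 7.39.

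The next comparisons follow the A/J response to days 5 and 7. The acute-phase gene Saa3 rose by 7.58 ± 0.99 at day 5 (adjusted p = 0.000505) and by 8.88 ± 0.99 at day 7 (adjusted p = 2.91e-05), from detection in 1 of 3 uninfected mice, and by 7.49 and 8.80 with values under an array's lowest detected signal raised to it. Uridine phosphorylase Upp1 rose by 5.16 and 5.64, and Batf2, a transcription factor of activated macrophages, by 4.56 and 4.90. The chemokine Ccl4 rose by 4.65 and 4.85, and Ifng by 4.66 and 4.78. Further rises at day 5 were in Cxcl1, Timp1, Gbp2 and Gbp2b, and at day 7 in Smpdl3b, Cstdc4 and Gpnmb, a glycoprotein of lipid-laden macrophages. At day 5 the red cell skeleton gene Tmod1 was at least 19.9-fold lower, and Tmcc2, Trim10, Dmtn and the carbonic anhydrase Car2 fell by 5.25, 5.05, 4.82 and 4.81. Fech, the last enzyme of haem synthesis, was at least 20.8-fold lower at day 5 and fell by 4.67 ± 0.72 at day 7, with its tested probe detected in 1 of 3 day 7 mice. The B cell IgE receptor Fcer2a fell by 4.49 ± 0.49 at day 7 (adjusted p = 2.90e-05), and Ccl21c, a lymphoid-homing chemokine, fell by 4.36.

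Of the 26 erythroid and haem genes, 18 fell at day 5 and 16 at day 7, with 23 and 24 lower when adjusted over the list alone and none higher. The list medians were −2.77 (adjusted p = 5.77e-20, and adjusted p = 0.139 with an estimated correlation) and −2.29 (adjusted p = 2.91e-12, and adjusted p = 0.216 with an estimated correlation). Beta globin Hbb-bt fell by 4.55 at day 5 and 3.99 ± 0.72 at day 7. Inflammatory monocyte markers rose in 9 of 15 genes at day 5 and 10 at day 7 (medians 2.97 and 3.25, adjusted p = 6.84e-07 and 7.18e-07, and adjusted p = 0.155 with an estimated correlation at both days). Examples were Ms4a6d at 4.63 and 4.92 and the C-type lectin Clec4d at 3.81 and 4.39. B cell markers had 2 of 18 members lower at day 5 and 13 at day 7, or 9 and 14 when adjusted over the list alone. Their medians were −0.89 (adjusted p = 2.87e-06, and adjusted p = 0.169 with an estimated correlation) and −1.62 (adjusted p = 1.80e-12, and adjusted p = 0.0630 with an estimated correlation). Cr2, the complement receptor of B cells, was at least 2.42-fold lower at day 7, and Cd22 fell by 2.22 ± 0.46.

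Interferon-inducible GTPases were higher in 9 of 13 genes at both days (medians 2.09 and 1.68, adjusted p = 2.82e-09 and 6.84e-07, and adjusted p = 0.128 and adjusted p = 0.169 with an estimated correlation). Cytokines rose in 8 of 20 genes at day 5 and 7 at day 7 (adjusted p = 8.44e-07 and 0.000633, and adjusted p = 0.155 and adjusted p = 0.313 with an estimated correlation). Il1rn, the interleukin 1 receptor antagonist, rose by 3.52 and 3.85, Tnf by 3.02 and 2.33, and Il10 was at least 4.30-fold higher at day 7. The day 7 call of Tnf ended without A/J uninfected replicates 1 or 3 or A/J day 7 replicates 2 or 3, with a highest adjusted p of 0.0757 without A/J day 7 replicate 2. Chemokines rose in 11 and 12 of 23 genes and fell in 2 and 3 (adjusted p = 0.000116 and 0.00253, and adjusted p = 0.231 and adjusted p = 0.350 with an estimated correlation), with Cxcl9 up by 3.79 and 4.11. Pattern recognition genes rose in 11 and 14 of 25 (adjusted p = 1.98e-09 and 2.46e-07, and adjusted p = 0.155 and adjusted p = 0.211 with an estimated correlation), including Tlr2 by 2.42 and 2.52 and the inflammatory caspase Casp4 by 1.97 and 2.07. Antimicrobial effectors of phagocytes rose in 5 and 7 of 12 and fell in 1 (adjusted p = 0.00102 and 0.000637, and adjusted p = 0.107 and adjusted p = 0.0936 with an estimated correlation). Arginase Arg1 was at least 3.38-fold higher at day 5 and at least 4.84-fold higher at day 7, and Ass1 rose by 3.68 and 4.04. The member that fell was Gch1, which makes the cofactor of nitric oxide synthase, by 2.71 and 2.00.

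Glycolysis genes rose in 7 of 14 at day 5 and 8 at day 7 (medians 0.78 and 1.06, adjusted p = 9.32e-05 and 6.92e-05, and adjusted p = 0.146 and adjusted p = 0.139 with an estimated correlation). Hexokinase Hk2 rose by 2.67 ± 0.43 at day 5 and 3.29 ± 0.43 at day 7, and the muscle-type pyruvate kinase Pkm by 1.46 and 1.72. Complement and acute-phase genes rose in 3 of 17 and 9 of 17 (adjusted p = 0.00365 and 0.000661, and adjusted p = 0.282 and adjusted p = 0.211 with an estimated correlation), with Serpina3n up by 2.35 and 3.16. Mitosis and DNA replication genes were lower as a list (medians −1.04 and −0.91, adjusted p = 1.34e-06 and 0.000106, and adjusted p = 0.349 and adjusted p = 0.458 with an estimated correlation), with 1 and 4 of 26 members past the test. MHC class II genes differed in the sign of median and mean at day 5 (0.52 and −0.12, adjusted p = 0.735), with H2-DMb2 down by 2.82 ± 0.82 and detected in 2 of 3 day 5 mice. This call ended without A/J uninfected replicates 2 or 3 or A/J day 5 replicates 1 or 2, with a highest adjusted p of 0.152. Among red pulp and marginal zone macrophage genes, Cd209b, a lectin of marginal zone macrophages, was at least 6.65-fold lower at day 5 and at least 6.09-fold lower at day 7, while Siglec1 rose by 2.57 and 1.70 (list adjusted p = 0.663 and 0.392). Type I interferon-stimulated genes rose as a list at day 5 (median 1.01, adjusted p = 0.000159, and adjusted p = 0.356 with an estimated correlation). At day 7 the list had a median of 1.22 (adjusted p = 0.0386, and adjusted p = 0.617 with an estimated correlation), and the antiviral gene Rsad2 fell by 2.25 ± 0.35. That call ended under median centring (adjusted p = 0.0712) and without AcB60 uninfected replicate 3, A/J uninfected replicate 2 or A/J day 7 replicates 2 or 3, with a highest adjusted p of 0.102.

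The counts were 732 higher and 400 lower at day 5 (2719 at an unadjusted p under 0.05), and 1185 higher and 653 lower at day 7 (3392). At day 5 the total of 1132 became 579, 600 and 553 without A/J uninfected replicates 1, 2 and 3 and 588 without A/J day 5 replicate 2, and at day 7 the total of 1838 became 1058, 1120 and 1092 without the uninfected replicates 1, 2 and 3. With the 4 doubted arrays left out (A/J day 5 replicate 1, A/J day 7 replicates 1 and 2 and AcB60 day 3 replicate 3), the totals were 2146 and 986, where the second sets 1 A/J day 7 mouse against 3 and assumes that it varies like the other groups. Array weights gave 3172 and 3271, and only the arrays compared gave 1175 at day 7. Median centring shifted the median of all genes to 0.23 at day 5 and 0.47 at day 7, where it gave 1942 higher and 354 lower.

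In AcB60 mice, day 3 against uninfected asks the same early question as in A/J. No gene passed limma's test (0 higher and 0 lower), with 644 at an unadjusted p under 0.05. The mice of the group differed from each other. Ifng stood at 10.43 and 10.05 in AcB60 day 3 replicates 1 and 2 and at 5.17 in replicate 3, beside 5.03 to 5.80 in uninfected AcB60 mice. Gbp2b stood at 11.15, 10.67 and 5.20, and Saa3 at 9.50, 11.23 and 5.53. Without replicate 3 Ifng had a change of 4.89 in place of 3.20, and 180 genes were higher and 40 lower, and 2 genes passed without AcB60 uninfected replicate 3. Array weights gave 227 genes and leaving out the 4 doubted arrays gave 676.

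As lists, the interferon-inducible GTPases were higher in AcB60 at day 3 (median 1.03, adjusted p = 1.31e-10, and adjusted p = 0.0986 with an estimated correlation), with 0 of 13 past limma's test over all genes and 7 when adjusted over the list alone. Gbp2b had 3.79 ± 0.93, Gbp2 2.47 ± 0.77, Gbp5 2.37 ± 0.63 and Igtp 1.56 ± 0.35. Type I interferon-stimulated genes were also higher (median 0.85, adjusted p = 9.36e-10, and adjusted p = 0.149 with an estimated correlation), with Oas2 at 2.40 ± 0.66 and Irf7 at 1.85 ± 0.62. Inflammatory cytokines (median 0.53, adjusted p = 1.05e-07) and neutrophil markers (median 0.69, adjusted p = 5.89e-06) were higher, with adjusted p = 0.139 and adjusted p = 0.254 with an estimated correlation. For the neutrophil list Prtn3 had 1.91 ± 0.50 and Lcn2 1.87 ± 0.82. B cell markers were lower (median −0.66, adjusted p = 4.50e-08, and adjusted p = 0.135 with an estimated correlation), with Cr2 at −1.51 ± 0.49 and Ms4a1, which encodes CD20, at −0.97 ± 0.39. T cell markers were lower as well (median −0.48, adjusted p = 7.76e-05, and adjusted p = 0.187 with an estimated correlation). Median centring shifted the median of all genes to 0.14 in this comparison. These list calls held with every array left out in turn, at other sizes. Without AcB60 day 3 replicate 3 the type I interferon median was 1.34, the neutrophil median 1.11, and Gbp2b, Gbp2, Oas2, Irf7 and Lcn2 had 5.69, 4.005, 3.61, 2.90 and 3.45. The type I interferon median was 0.45 without AcB60 day 3 replicate 2, and the neutrophil median was 0.36, 0.41 and 0.46 without AcB60 day 3 replicate 1, AcB60 day 3 replicate 2 and AcB60 uninfected replicate 3. Lcn2 had 1.12 and 1.03 without AcB60 day 3 replicates 1 and 2.

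By day 7 the AcB60 spleen had changed in many genes. Saa3 rose by 7.90 ± 0.99 (adjusted p = 0.000282) and Gbp2b by 6.80 ± 0.93 (adjusted p = 0.000420), each from detection in 1 of 3 uninfected mice, and by 7.79 and 6.58 with values under an array's lowest detected signal raised to it. Lcn2, which binds bacterial siderophores, rose by 5.71 ± 0.82 and haptoglobin, Hp, by 5.33 ± 1.12. Chil1 rose by 5.89 and Ifng by 5.24, each detected in 1 of 3 uninfected mice, coagulation factor F10 by 5.65 and Upp1 by 5.14. The lymphoid chemokines Ccl21c, Ccl21b and Ccl21a fell by 4.19, 4.02 and 3.74 ± 0.45. Alas2, the erythroid enzyme that starts haem synthesis, fell by 3.59 ± 0.78, Hbb-bt by 3.25 ± 0.72, Tmcc2 by 4.34, and Siglech, a marker of plasmacytoid dendritic cells, by 3.32 ± 0.58. Of these calls only that of Hbb-bt ended with 1 array left out (adjusted p = 0.0539 without AcB60 uninfected replicate 3).

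Neutrophil markers rose in 13 of 20 genes, and 16 when adjusted over the list alone (median 2.10, adjusted p = 1.01e-16, and adjusted p = 0.0650 with an estimated correlation). Prtn3, a granule protease, rose by 4.09 ± 0.50 and the formyl peptide receptor Fpr2 by 3.88 ± 0.76. Inflammatory monocyte markers rose in 10 of 15 (median 3.14, adjusted p = 3.44e-14, and adjusted p = 0.0593 with an estimated correlation), with Ms4a6d up by 5.22 and Chil3 by 4.52. Phagocyte antimicrobial effectors rose in 6 of 12 (median 1.33, adjusted p = 5.12e-06) and kept their call, with adjusted p = 0.0443 with an estimated correlation. Arg1 was at least 4.56-fold higher and Nos2, inducible nitric oxide synthase, at least 2.28-fold higher, a call that ended without AcB60 day 7 replicate 1 (adjusted p = 0.0527). The GTPases rose in 9 of 13 (median 2.20, adjusted p = 1.52e-11, and adjusted p = 0.0792 with an estimated correlation), complement and acute-phase genes in 6 of 17 (median 1.39, adjusted p = 8.97e-09, and adjusted p = 0.0642 with an estimated correlation), and glycolysis genes in 7 of 14 (median 1.10, adjusted p = 7.34e-08, and adjusted p = 0.0630 with an estimated correlation).

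B cell markers fell in 12 of 18 genes (median −1.19, adjusted p = 1.43e-11, and adjusted p = 0.0672 with an estimated correlation), such as Cr2 by 2.39 ± 0.49 and Cd22 by 1.95 ± 0.46. T cell markers fell in 4 of 19, or 8 when adjusted over the list alone (median −0.69, adjusted p = 0.000437, and adjusted p = 0.231 with an estimated correlation), with Cd8b1 down by 1.82 ± 0.29 and the homing receptor Ccr7 by 1.61 ± 0.44. The call of Ccr7 ended without any 1 of the 6 arrays compared (adjusted p up to 0.128, without AcB60 uninfected replicate 1), and that of Cd22 without AcB60 uninfected replicates 1 or 2 or AcB60 day 7 replicates 2 or 3 (up to 0.0933, without AcB60 day 7 replicate 2). Erythroid genes fell in 4 of 26 (median −1.02, adjusted p = 5.11e-05, and adjusted p = 0.502 with an estimated correlation), a call that ended without AcB60 uninfected replicate 3 (median −0.25, adjusted p = 0.0943), while the median was −1.88 without AcB60 uninfected replicate 2. The erythroid list mean of the 3 uninfected AcB60 mice was 10.3, 8.99 and 11.6. Dendritic cell markers were lower (median −0.64, adjusted p = 0.0401, and adjusted p = 0.364 with an estimated correlation), which ended without AcB60 uninfected replicate 2 (median −0.38, adjusted p = 0.178). NK and cytotoxic lymphocyte genes did not pass as a list (median 0.40, adjusted p = 0.161), with perforin, Prf1, down by 1.72 ± 0.36 and Gzmk at least 2.13-fold higher.

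In all, 440 genes were higher and 317 lower at day 7 in AcB60 (2254 at an unadjusted p under 0.05). The total of 757 became 370, 475 and 489 without AcB60 uninfected replicates 1, 2 and 3, and 342 and 397 without AcB60 day 7 replicates 2 and 3. Leaving out the 4 doubted arrays gave 1900 and the 2 with disagreeing probes 1361. Array weights gave 1357, only the arrays compared 1280 and median centring 481 (310 higher and 171 lower). Between the strains, 358 genes were higher at day 7 in both, against 47.6 for independent lists, and 143 were lower in both, against 18.9, with 0 called in opposite directions by limma's test. The changes of all 10953 features correlated across genes with r = 0.647 at day 3 and 0.616 at day 7 (Spearman's rho 0.562 and 0.523). Without AcB60 day 3 replicate 1 the day 3 value was 0.424, and genes are not independent replicates.

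**Figure D3:**
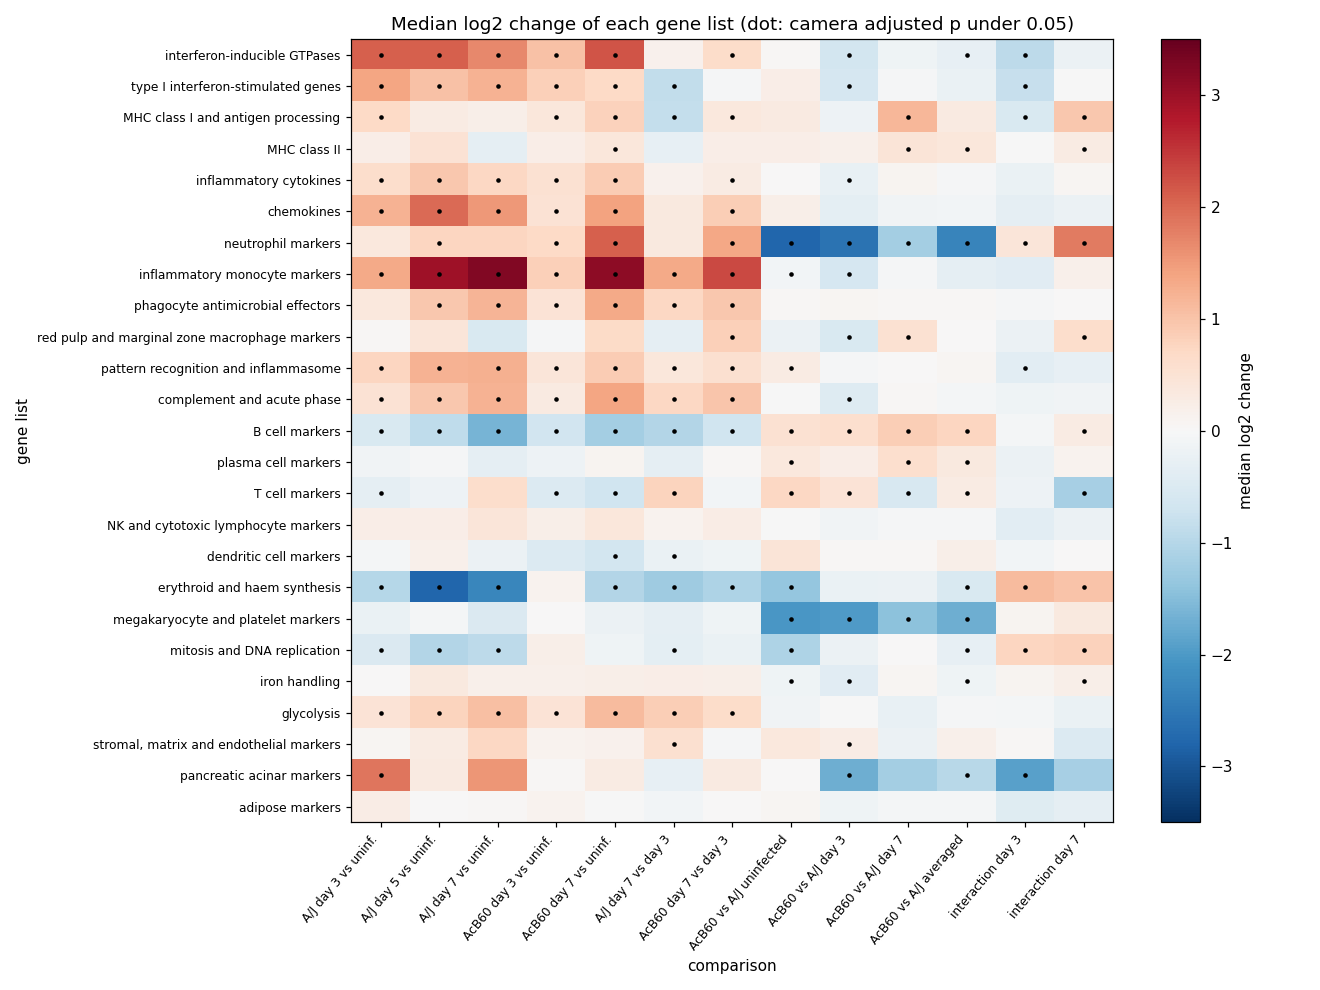
Median log2 change of the 25 gene lists (vertical axis) in the 13 contrasts (horizontal axis), as colour, with a dot where camera's adjusted p is under 0.05. The erythroid list stands at −2.77 in A/J at day 5 and the neutrophil list at −2.78 between the uninfected strains.

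Day 7 against day 3 asks how the response moved on within each strain. In A/J, Saa3 rose by 4.49 ± 0.99, Gpnmb by 4.14, Chil3 by 4.05 ± 0.68 and the neutrophil gene Stfa1 by 3.63 ± 0.70. Trem2, a lipid receptor of macrophages detected in 1 of 3 day 3 mice, rose by 3.54 ± 0.30 (adjusted p = 6.84e-06). The survival gene Bcl2l1, detected in 1 of 3 day 7 mice, fell by 3.91, the ISG15-conjugating enzyme Ube2l6 by 3.66, Tmcc2 by 3.58, Fcer2a by 3.45 ± 0.49 and Stard10 by 3.05. Type I interferon-stimulated genes fell as a list (median −0.85, adjusted p = 7.64e-07, and adjusted p = 0.216 with an estimated correlation), with 2 of 25 members past the test, Rsad2 down by 2.67 ± 0.35 and Isg15 by 2.39 ± 0.55. B cell markers fell in 5 of 18 (median −1.03, adjusted p = 5.09e-11, and adjusted p = 0.0740 with an estimated correlation). T cell markers rose in 3 of 19, or 9 when adjusted over the list alone (median 0.79, adjusted p = 8.31e-05, and adjusted p = 0.187 with an estimated correlation), with Cd6 up by 1.85 ± 0.30 and Cd5 by 1.58 ± 0.38. MHC class I genes were lower (median −0.83, adjusted p = 0.0114, and adjusted p = 0.458 with an estimated correlation) until A/J day 7 replicate 1 was left out (median −0.06, adjusted p = 0.449), the array on which 47.0% of probe pairs disagreed, and had a median of −1.48 without A/J day 7 replicate 3. Ube2l6 fell by 2.37 without A/J day 7 replicate 1. Without A/J day 3 replicates 1 or 2 or A/J day 7 replicate 1 the calls of Saa3, Bcl2l1, Ube2l6, Tmcc2, Stard10, Isg15 and Cd5 each ended, with adjusted p of 0.119, 0.133, 0.124, 0.0979, 0.0741, 0.0840 and 0.119 without A/J day 3 replicate 2. Some ended without a further array of A/J day 3 replicate 3 or A/J day 7 replicates 2 and 3 as well, Ube2l6 at 0.0519, Bcl2l1 at 0.106, Stard10 at 0.0575, Cd5 at 0.0586 and 0.0520, and Tmcc2 at 0.0507.

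The A/J step from day 3 to day 7 gave 248 higher and 64 lower genes (1944 at an unadjusted p under 0.05). The total of 312 became 117 and 124 without A/J day 3 replicates 1 and 2, 157 without A/J day 7 replicate 1 and 785 without A/J day 7 replicate 3, and a fit to only the 6 arrays compared left 1. With the 4 doubted arrays left out, which leaves 1 A/J day 7 mouse, it was 77, and 205 without the 2 with disagreeing probes. Median centring shifted the median of all genes to 0.31 and gave 308 higher and 35 lower.

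In AcB60, Saa3 rose by 4.68 ± 0.99 from day 3 to day 7, Lcn2 by 3.84 ± 0.82, Gpnmb by 3.29 and Aoah, which inactivates bacterial lipopolysaccharide, by 3.18. Chil3, whose tested probe was detected in 0 of 3 day 3 mice, was at least 19.1-fold higher. The potassium channel Kcnc4 fell by 3.71, Alas2 by 3.47 ± 0.78 and Ltbp4 by 3.04 ± 0.33 (adjusted p = 0.000171), and Erich2 was at least 7.78-fold lower. Neutrophil markers rose in 2 of 20 genes, or 13 when adjusted over the list alone (median 1.36, adjusted p = 2.51e-15, and adjusted p = 0.0740 with an estimated correlation). Monocyte markers rose in 3 of 15 (median 2.30, adjusted p = 7.38e-13, and adjusted p = 0.0630 with an estimated correlation). Erythroid genes fell in 1 of 26, or 6 when adjusted over the list alone (median −1.07, adjusted p = 1.75e-08, and adjusted p = 0.329 with an estimated correlation). The GTPase list was higher (median 0.65, adjusted p = 3.60e-05, and adjusted p = 0.242 with an estimated correlation), which ended without AcB60 day 3 replicate 3 (median 0.13, adjusted p = 0.0774) and had a median of 1.23 without AcB60 day 3 replicate 2. Without AcB60 day 3 replicate 3 the monocyte and erythroid medians were 1.07 and −0.61, and Saa3 and Lcn2 rose by 3.07 and 2.26. Of the genes above, only Chil3, Aoah, Kcnc4 and Ltbp4 passed with each of the 6 arrays left out. The calls of Saa3, Gpnmb, Alas2 and Erich2 ended without AcB60 day 3 replicate 3 (adjusted p = 0.132, 0.0608, 0.217 and 0.0723). Other arrays ended them too, with AcB60 day 7 replicate 1 for Saa3, Lcn2, Alas2 and Gpnmb (0.176, 0.139, 0.193 and 0.0793), replicate 2 for Saa3, Lcn2 and Alas2 (0.136, 0.169 and 0.194), replicate 3 for these and Erich2 (0.0774, 0.102, 0.0731 and 0.0518), and AcB60 day 3 replicates 1 and 2 for Alas2 (0.0532 and 0.105). Here 36 genes were higher and 31 lower (1264 at an unadjusted p under 0.05). The total of 67 became 133, 42 and 21 without AcB60 day 3 replicates 1, 2 and 3, and 30, 22 and 22 without AcB60 day 7 replicates 1, 2 and 3. Array weights gave 363, only the arrays compared 34 and leaving out the 2 arrays with disagreeing probes 193. Median centring gave 16 higher and 24 lower and shifted the median of all genes to −0.16.

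The strain comparisons ask which genes AcB60 and A/J spleens express differently, whatever the infection. Averaged over uninfected, day 3 and day 7 mice, with 9 mice per strain, 82 genes were higher and 89 lower in AcB60 (1097 at an unadjusted p under 0.05). The adaptor gene Samsn1, a brake on B cell activation, was higher by 5.77 ± 0.16 (adjusted p = 3.77e-14), at 10.21 to 11.62 in AcB60 and 4.77 to 5.57 in A/J mice of these groups, of which 1 of 9 had it detected. Emb, a cell adhesion glycoprotein, was at least 12.4-fold higher, the mitochondrial import gene Chchd4 at least 9.87-fold and the signal transducer of the interleukin 6 receptor, Il6st, at least 6.57-fold. Erdr1 was higher by 4.04, and Cdk5rap1, Sdc4 and Rmdn3 by 2.70 each. A second tested probe of Rmdn3 had 0.29 (unadjusted p = 0.563), and 2 further probes of Cdk5rap1 had 1.33 and 2.33. In the other direction, Tmem87a was lower by −4.69, Gbp2b by −3.76 ± 0.54 and Serpina3b by −2.59, detected in 4, 6 and 4 of the 9 AcB60 mice. By the rule for naming, these genes had all 3 AcB60 mice on the same side of all 3 A/J mice in every condition. Each of these genes kept its call with every array left out in turn. Of further tested probes of called genes, 4 of 7 on chromosome 2 and 29 of 48 elsewhere changed the same way at an unadjusted p under 0.05, and 6 and 41 had the same sign. Of the genes named in this paragraph, only Rmdn3 and Cdk5rap1 had such probes. For the others, a probe that matches the parental alleles unequally could not be told from a difference in expression.

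Neutrophil markers were lower in AcB60 in 13 of 20 measured members, or 14 when adjusted over the list alone (median −2.30, adjusted p = 8.44e-38), and this held with an estimated correlation (adjusted p = 0.00790). Myeloperoxidase, Mpo, had −3.51 ± 0.29 (adjusted p = 4.62e-07), cathepsin G, Ctsg, −3.49 ± 0.29, the cathelicidin Camp −3.04 ± 0.26 and lactoferrin, Ltf, −2.98. Mpo, Ctsg and the protease Prtn3 (−3.03 ± 0.29) are primary granule genes transcribed in granulocyte precursors. Platelet and megakaryocyte genes were lower in 8 of 11 (median −1.70, adjusted p = 5.24e-24, and adjusted p = 0.00790 with an estimated correlation). Treml1, a receptor of platelet granules, had −2.40 ± 0.23 (adjusted p = 1.98e-06) and the von Willebrand receptor subunits Gp5 and Gp1bb −2.14 ± 0.28 and −2.13 ± 0.33. B cell markers were higher in AcB60 in 6 of 18, or 14 when adjusted over the list alone (median 0.75, adjusted p = 2.83e-16, and adjusted p = 0.0443 with an estimated correlation), with Fcer2a at 1.39 ± 0.28 and Blk at 0.87 ± 0.16. Further tested probes had 0.46 and 0.64 for Fcer2a (unadjusted p = 0.189 and 0.0784) and 0.21 and 1.10 for Blk (unadjusted p = 0.432 and 1.38e-06). Plasma cell markers were higher in 2 of 10 (median 0.34, adjusted p = 9.32e-05, and adjusted p = 0.139 with an estimated correlation), with Mzb1 at 0.94 ± 0.17. Dendritic cell markers did not pass as a list (adjusted p = 0.286), and Cd207, langerin, had −1.40 ± 0.21. The acinar list was lower (median −0.98, adjusted p = 8.31e-05, and adjusted p = 0.463 with an estimated correlation) and turned to a median of 0.0469 without the 2 arrays that carried acinar transcripts, from −0.42 without A/J day 3 replicate 3 alone and −0.52 without A/J day 7 replicate 2 alone. No array left out moved the averaged count of 171 by over 1.5 times, while median centring gave 111, array weights 331 and a minimum change of 1 log2 unit 101.

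**Figure D4:**
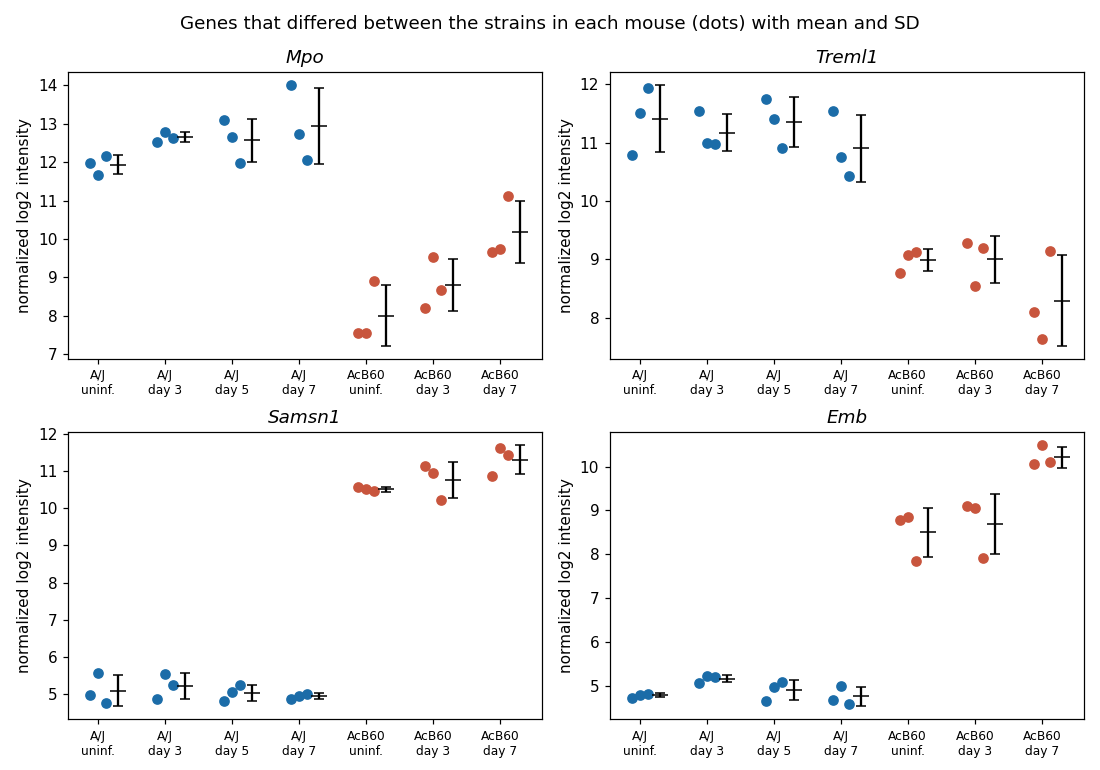
Normalized log2 expression on the vertical axis for Mpo, Treml1, Samsn1 and Emb in each of the 7 groups, with 1 dot per mouse and the mean ± SD of 3 mice. Mpo stood at 7.54 to 8.91 in uninfected AcB60 and 11.66 to 12.17 in uninfected A/J mice, and Samsn1 at 10.45 to 10.58 against 4.77 to 5.57.

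Among uninfected mice, 20 genes were higher and 30 lower in AcB60 (727 at an unadjusted p under 0.05). Samsn1 was higher by 5.41 ± 0.28 (adjusted p = 1.89e-09), with detection in 1 of 3 A/J mice, and the neutrophil elastase gene Elane was lower at −4.04 ± 0.46 with Lcn2 at −4.17 ± 0.82. The call of Lcn2 ended without any 1 of the 6 mice except AcB60 uninfected replicate 3, with a highest adjusted p of 0.153 without A/J uninfected replicate 3. Neutrophil markers were lower in 11 of 20 (median −2.78, adjusted p = 8.61e-43, and adjusted p = 0.00790 with an estimated correlation) and megakaryocyte markers in 3 of 11, or 10 when adjusted over the list alone (median −2.03, adjusted p = 4.06e-22, and adjusted p = 0.00790 with an estimated correlation). The erythroid list was lower (median −1.36, adjusted p = 3.44e-14, and adjusted p = 0.187 with an estimated correlation) with 0 of 26 members past limma's test, such as Car2 at −2.53 ± 1.12 and Fech at −2.17 ± 0.72. The erythroid median was −0.68 without AcB60 uninfected replicate 2, where Car2 and Fech had −1.28 and −1.37, and −2.11 without AcB60 uninfected replicate 3, where Fech passed (adjusted p = 0.0426). T cell markers were higher as a list (median 0.73, adjusted p = 1.75e-08, and adjusted p = 0.0792 with an estimated correlation) with Zap70 at 1.05 ± 0.34 and Cd5 at 1.02 ± 0.38, and Zap70 passed without AcB60 uninfected replicate 3 (adjusted p = 0.0428). The total of 50 became 32 and 96 without AcB60 uninfected replicates 1 and 3 and 27 without A/J uninfected replicate 3. Array weights gave 230, leaving out the 4 doubted arrays 102, only the arrays compared 82 and median centring 33.

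At day 3, 20 genes were higher and 24 lower in AcB60 (496 at an unadjusted p under 0.05). Ctsg had −4.05 ± 0.51, Mpo −3.85 ± 0.50 and Ltf −3.49 ± 0.37, and neutrophil markers were lower in 8 of 20 (median −2.59, adjusted p = 7.50e-38, and adjusted p = 0.00790 with an estimated correlation). Megakaryocyte markers were lower in 3 of 11 (median −1.99, adjusted p = 2.60e-21, and adjusted p = 0.00799 with an estimated correlation). GTPases (median −0.65, adjusted p = 9.86e-08) and type I interferon-stimulated genes (median −0.60, adjusted p = 4.94e-09) were lower, with adjusted p = 0.154 and adjusted p = 0.155 with an estimated correlation. Both calls ended without AcB60 day 3 replicate 3, at medians of −0.13 and −0.09 (adjusted p = 0.0734 and 0.129), and there the neutrophil median was −1.71. The GTPase median was −1.004 and −1.04 without AcB60 day 3 replicates 1 and 2. The acinar list was lower (median −1.70, adjusted p = 4.87e-09, and adjusted p = 0.254 with an estimated correlation) until A/J day 3 replicate 3 was left out (median −0.08, adjusted p = 0.269), and had −2.62 without A/J day 3 replicate 1. The total of 44 became 28 without AcB60 day 3 replicate 2 and 25 without A/J day 3 replicate 2, and 18 with only the 13-week AcB60 mouse, whose spread is assumed to be that of the other groups. Array weights gave 98, and leaving out the 2 arrays with disagreeing probes or the 4 doubted arrays gave 75 and 67.

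At day 7, 30 genes were higher and 37 lower in AcB60 (1425 at an unadjusted p under 0.05). Samsn1 was at least 49.7-fold and Emb at least 23.4-fold higher. Treml1 was lower at −2.61 ± 0.39 and the neuronal enolase Eno2 at −3.03 ± 0.32. Megakaryocyte markers were lower in 4 of 11 (median −1.44, adjusted p = 1.35e-07, and adjusted p = 0.121 with an estimated correlation) and neutrophil markers in 3 of 20 (median −1.19, adjusted p = 2.79e-06, and adjusted p = 0.244 with an estimated correlation). B cell markers were higher in 2 of 18, or 9 when adjusted over the list alone (median 0.87, adjusted p = 7.86e-12, and adjusted p = 0.0650 with an estimated correlation). The MHC class I list was higher (median 1.17, adjusted p = 0.000247, and adjusted p = 0.280 with an estimated correlation) with 0 of 18 past limma's test, such as H2-T23 at 2.36 ± 0.85 and H2-K1 at 1.66 ± 0.54. Its median was 0.24 without A/J day 7 replicate 1 (adjusted p = 0.0473), with H2-T23 at 1.38 and H2-K1 at 1.09, and 1.76 without A/J day 7 replicate 3, where these 2 genes passed (adjusted p = 0.0335 and 0.0360). The neutrophil median was −0.71 without A/J day 7 replicate 2. The total of 67 became 27, 25 and 39 without AcB60 day 7 replicates 1, 2 and 3, and 43, 20 and 385 without A/J day 7 replicates 1, 2 and 3. Array weights gave 103, only the arrays compared 4, leaving out the 2 arrays with acinar transcripts 17 and leaving out the 4 doubted arrays, with 1 A/J day 7 mouse, 22. Median centring gave 13 higher and 34 lower and moved the median of all genes from −0.11 to −0.48.

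The interaction contrasts ask whether infection changed a gene differently in the strains. At day 3 no gene passed limma's test (0, with 124 at an unadjusted p under 0.05), and 1 passed without AcB60 day 3 replicate 3 and 1 without the 4 doubted arrays. At day 7 only Eno2, a glycolytic enzyme best known from neurons, passed of 970 genes at an unadjusted p under 0.05, with −3.64 ± 0.45 (adjusted p = 0.00188). It rose in A/J by 2.63 ± 0.32, from 5.93 to 6.12 in uninfected mice to 8.38 to 9.06 at day 7, and stood at 6.52 to 6.83 and 5.51 to 5.87 in AcB60. The day 7 count of 1 became 3 without AcB60 uninfected replicate 3, 2 without AcB60 day 7 replicate 2, 2 without A/J uninfected replicate 2 22 without A/J day 7 replicate 3, and 2 without AcB60 day 3 replicate 3 or with only the arrays compared. Median centring moved the median of all genes from −0.15 to −0.55 at day 7.

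Neutrophil markers rose more in AcB60 than in A/J by day 7 (median interaction 1.82, adjusted p = 1.75e-11, and adjusted p = 0.128 with an estimated correlation), with 0 of 20 past limma's test over all genes and 8 when adjusted over the list alone. Elane had 2.78 ± 0.65, Ngp 4.73 ± 1.48 and Lcn2 3.64 ± 1.16. The neutrophil list mean began at 7.49 to 7.87 in uninfected AcB60 mice and at 10.04 to 10.67 in uninfected A/J mice. At day 7 it was 9.98 to 10.37 in AcB60 and 10.91 to 11.41 in A/J, so AcB60 stayed lower. In A/J itself 6 of the 20 genes rose by day 7, such as Stfa1 by 3.74 ± 0.70, and the list did not pass (median 0.75, adjusted p = 0.110). At day 5 the A/J list had a median of 0.76 with 3 of 20 members past the test (adjusted p = 0.0468, and adjusted p = 0.640 with an estimated correlation). That call ended without AcB60 uninfected replicate 3, AcB60 day 7 replicate 1, A/J uninfected replicates 1 or 2, any 1 of the 3 A/J day 3 mice or A/J day 5 replicates 1 or 2, with a highest adjusted p of 0.205 without A/J day 5 replicate 2. T cell markers moved the other way (median −1.17, adjusted p = 8.89e-09, and adjusted p = 0.0740 with an estimated correlation), 0 of 19 past limma's test over all genes and 6 when adjusted over the list alone, with Zap70 at −1.85 ± 0.48, Cd6 at −1.74 ± 0.42 and Cd5 at −1.88 ± 0.53. The erythroid list had medians of 1.12 at day 3 (adjusted p = 5.79e-11, and adjusted p = 0.246 with an estimated correlation) and 1.00 at day 7 (adjusted p = 1.25e-06, and adjusted p = 0.406 with an estimated correlation). Type I interferon-stimulated genes had −0.80 at day 3 (adjusted p = 5.65e-08, and adjusted p = 0.183 with an estimated correlation). These calls held with every array left out in turn, at other sizes. The erythroid medians at days 3 and 7 were 0.49 and 0.40 without AcB60 uninfected replicate 2 and 1.86 and 1.81 without AcB60 uninfected replicate 3, and at day 3 0.57 without AcB60 day 3 replicate 3 and 0.58 without A/J day 3 replicate 3. The type I interferon median was −0.28 without AcB60 day 3 replicate 3. The GTPase interaction at day 3 (median −0.90, adjusted p = 1.03e-05, and adjusted p = 0.211 with an estimated correlation) ended without that array (median −0.04, adjusted p = 0.872).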

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

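Chosen after the results were seen were all tests on AcB60 day 3 replicate 3, and the tests of degradation in a pair of A/J arrays and in A/J day 7 replicate 2 alone, of pancreatic tissue and of a more advanced infection in A/J day 7 replicate 2 alone. A difference between the strains in the response to infection, by the interaction test, drew attention to 1 gene and 17 lists. Eno2 had −3.64 at day 7 (adjusted p = 0.00188). With camera at the preset correlation, 8 lists differed at day 3. Interferon-inducible GTPases had a median of −0.90 (adjusted p = 1.03e-05), type I interferon-stimulated genes −0.80 (adjusted p = 5.65e-08), MHC class I −0.53 (adjusted p = 0.0164), pattern recognition −0.36 (adjusted p = 0.00175) and pancreatic acinar markers −1.89 (adjusted p = 1.43e-06). Neutrophil markers had 0.44 (adjusted p = 0.0113), erythroid genes 1.12 (adjusted p = 5.79e-11) and mitosis genes 0.74 (adjusted p = 1.11e-07). With an estimated correlation the adjusted p of these 8 lists lay between 0.183 and 0.557. Without AcB60 day 3 replicate 3 the GTPase, MHC class I and pattern recognition calls ended (adjusted p = 0.872, 0.676 and 0.883). The MHC class I call also ended without A/J uninfected replicate 2 or A/J day 3 replicate 1 (0.0661 and 0.118) and the pattern recognition call without A/J day 3 replicate 3 (0.122). The acinar call ended without A/J day 3 replicate 3 (adjusted p = 0.595), the mitosis call without AcB60 uninfected replicate 2 (adjusted p = 0.0951), and the neutrophil call without AcB60 day 3 replicates 1 or 2 (0.285 and 0.664), AcB60 uninfected replicate 3 (0.0966), A/J uninfected replicate 3 (0.152) or A/J day 3 replicate 3 (0.0797). Calls that held moved in size. Without AcB60 uninfected replicate 2 the medians were 0.49 for erythroid genes, −0.33 for MHC class I and −0.21 for pattern recognition. Without AcB60 uninfected replicate 3 they were 1.86 for erythroid genes, 1.27 for mitosis genes and −0.54 for pattern recognition, and pattern recognition had −0.64 without AcB60 day 3 replicate 1. Without AcB60 day 3 replicate 3 they were −0.28 for type I interferon-stimulated genes, 0.57 for erythroid genes, 0.44 for mitosis genes and 0.86 for neutrophil markers, and without A/J day 3 replicate 3 they were 0.58 for erythroid and 0.45 for mitosis genes.

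At day 7, 9 lists differed between the strains by the same test. Neutrophil markers had a median of 1.82 (adjusted p = 1.75e-11), T cell markers −1.17 (adjusted p = 8.89e-09), erythroid genes 1.00 (adjusted p = 1.25e-06), mitosis genes 0.80 (adjusted p = 1.25e-06) and MHC class I 0.94 (adjusted p = 0.0288). Red pulp macrophage markers had 0.60 (adjusted p = 0.0221), MHC class II 0.30 (adjusted p = 0.0332), B cell markers 0.29 (adjusted p = 0.0117) and iron handling 0.20 (adjusted p = 0.0363). Under median centring the medians of MHC class II, B cell markers and iron handling were −0.19, −0.07 and −0.17, with the median of all genes at −0.55. Camera's direction, set against all other named genes, stayed the same, and the MHC class II call ended (adjusted p = 0.0657). With an estimated correlation the adjusted p of these 9 lists lay between 0.0740 and 0.544. Leaving out A/J day 7 replicate 1 ended the MHC class I, MHC class II, iron and red pulp calls (adjusted p = 0.518, 0.170, 0.116 and 0.0562). Leaving out AcB60 uninfected replicate 3 ended the red pulp and B cell calls (adjusted p = 0.375 and 0.245) and those of MHC class I, MHC class II and iron (0.137, 0.132 and 0.102). The MHC class I call also ended without AcB60 day 3 replicate 3, AcB60 day 7 replicate 1 or A/J uninfected replicate 3 (0.0658, 0.119 and 0.0604), that of MHC class II without A/J uninfected replicate 2 (0.0781) and that of B cell markers without A/J day 7 replicate 2 (0.0742). The iron call ended as well without AcB60 day 7 replicate 2, A/J uninfected replicate 1 or A/J day 7 replicate 3 (0.0677, 0.0501 and 0.0626). Other calls held at another size. Without AcB60 uninfected replicate 2 the medians were 0.33 for mitosis genes (adjusted p = 0.0113), 0.40 for erythroid genes, 0.48 for B cell markers and 0.36 for iron handling, and without AcB60 uninfected replicate 3 they were 1.31 for mitosis and 1.81 for erythroid genes. MHC class I had 1.48 and 1.52 without A/J day 7 replicates 2 and 3, MHC class II 0.63 and 0.49 without AcB60 day 7 replicate 3 and A/J day 7 replicate 2, and B cell markers 0.15 and 0.45 without A/J uninfected replicates 2 and 3.

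The infection response was missing in AcB60 day 3 replicate 3, whose level over 35 genes that rose in A/J by day 3 was 7.88, against 10.2 and 10.1 in its group. A swap with an uninfected AcB60 mouse would need an uninfected array with a response, and the highest such array stood at 8.18, so the tables argue against it. Poor RNA or array quality is also argued against, since only 2.83% of its probe pairs disagreed. A single wrong label and an infection that did not take both predict a level of 7.88 among uninfected mice. The level cannot tell them apart, and bacterial counts were not used here. The number in the sample title of this array, 131, lay among those of the uninfected mice (119 to 136). The other infected mice had 91 to 112. This goes with a wrong label, but the labels do not say what the numbers stand for, and this was not tested. Without this array 220 genes passed the day 3 test in AcB60 in place of 0.

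A/J day 5 replicate 1 and A/J day 7 replicates 1 and 2 stood apart from the other infected mice in probe-pair agreement. Degradation shared by all 3 predicts like deviations between probes of a gene. The lowest correlation between the arrays was 0.238, below the level set in advance for shared degradation. It lay between the highest correlations of its 2 arrays with uninfected mice, 0.207 and 0.346, so degradation of all 3 stays open. A more advanced infection predicts deviations along the AcB60 day 7 response. The lowest correlation was −0.212, but disagreeing probes enter it, so this explanation stays open. For the pair A/J day 5 replicate 1 and A/J day 7 replicate 1 the probe deviations correlated at 0.854 across genes, above 0.448 for the closest uninfected array, so degradation may account for these 2 samples. For A/J day 7 replicate 2 alone degradation stays open, since its probe deviations correlated at 0.463 with A/J day 5 replicate 1 and at 0.238 with A/J day 7 replicate 1, against 0.207 for the closest uninfected array. Pancreatic tissue is argued against for the 3 as a set, since the smallest excess of the acinar list was 0.10 log2, but it stays a candidate source for A/J day 7 replicate 2 with an excess of 3.88, where Reg1 stood at 12.16 and Pnliprp1 at 11.62, with 2 of the 14 list genes detected on all uninfected arrays and 0 held by another list. Whether A/J day 7 replicate 2 was also further infected stays open, as its deviation correlated at −0.00550 with the AcB60 day 7 response.

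Genes that differ between the strains crowded on chromosome 2, where 32 of 807 tested genes were called (3.97%, against 1.34% elsewhere), 23 of them higher in AcB60. Probes that match the parental alleles unequally would leave further probes of the same genes unmoved, and 57.1% of them (4 of 7, from 6 genes) changed the same way at an unadjusted p under 0.05, with an exact 95% interval of 18.4% to 90.1%. By sign alone it was 6 of 7. With so few further probes this explanation stays open, and on other chromosomes the share was 60.4% (29 of 48). A donor segment of C57BL/6J origin on chromosome 2 may account for the crowding, but genotypes were not used here and this was not tested.

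Other splits of the 6 arrays of a comparison were counted as well. For 9 of the comparisons of 3 against 3 mice, 1 of 10 splits, the real one, gave as many calls, and the highest of the other splits gave 0. These are the infection comparisons in A/J at days 3, 5 and 7 (39, 1132 and 1838 calls) and in AcB60 at day 7 (757), day 7 against day 3 (312 in A/J and 67 in AcB60) and the strains uninfected, at day 3 and at day 7 (50, 44 and 67). In AcB60 at day 3 the real count is 0, which all 10 of 10 splits reach whatever the data, so the count of splits says nothing about chance. The highest gave 73, and that split set AcB60 uninfected replicates 1 and 3 with AcB60 day 3 replicate 3 against the others, which points to a structure of the samples. In these designs the splits are too few for a share under 0.05.

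For the averaged strain contrast, chance would seldom give as many calls. Only the real assignment, 1 of 100 draws, gave 171 calls, and the highest of the others gave 78. This is the smallest share that 100 draws can give, so it makes chance unlikely but does not exclude it. For the interaction at day 7, 10 of 100 draws gave at least the real 1, and the highest gave 28. The draws shuffled the strain within each condition without removing the strain difference. They therefore cannot decide about chance here, which stays open. At day 3 the real count is 0, which all 100 of 100 draws reach whatever the data, so these draws say nothing about chance, and the highest gave 234. In a draw that keeps the strains in 1 condition and exchanges them in the other, the strain difference appears as an interaction. This alone can give high counts, so they do not point to a further structure of the samples.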

How the results depend on the processing

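Chosen after the data were seen were the sets of left-out arrays described by their measured values, the list tests with each array left out, the tests of pairs within 10 genes and of the largest chromosome excess, the values raised to the lowest detected signal and the permutation of replicate numbers. Of the named genes' values under other settings, 4594 kept direction and side of the threshold, 455 no longer passed and 48 newly passed, and with 1 array left out the numbers were 2445, 647 and 16. Of the list values, 918 kept both, 295 no longer passed and 11 turned, and 101 of the 153 list calls held with each of 21 arrays left out in turn. Signal over background limits genes not detected in a group, whose changes are lower bounds. In 48 named changes of genes detected on only some arrays of a group, raising values under an array's lowest detected signal to it moved the change by at most 0.63, in Bcl2l1. Leaving out an array of a group outside a contrast keeps its log2 changes, so it moves gene calls only through the spread shared by all groups. Unless stated, the cause of other shifts was not tested.

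Array weights gave 823, 3172 and 3271 genes for A/J at days 3, 5 and 7, 227 and 1357 for AcB60 at days 3 and 7, 363 for AcB60 day 7 against day 3, 230, 98 and 103 for the strains uninfected, at day 3 and at day 7, and 331 for the averaged contrast. Median centring gave 12 for A/J day 3, 481 for AcB60 day 7, 40 for AcB60 day 7 against day 3, 33 for the uninfected strains and 111 for the averaged contrast. Without a detection filter A/J day 3 had 20, with more features tested. Only the arrays compared gave 367 for A/J day 3, 1175 for A/J day 7, 1280 for AcB60 day 7, 1 for A/J day 7 against day 3, 34 for AcB60 day 7 against day 3, 82 and 4 for the strains uninfected and at day 7, and 2 for the interaction at day 7. A minimum change of 1 log2 unit left 101 in the averaged contrast, by its construction, and 2 neighbouring pairs of called genes (p = 0.214 by permutation) in place of 7 (p = 0.0108). With only the 13-week AcB60 mouse at day 3, whose spread was assumed to be that of the other groups, the strains differed in 18 genes.

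Without the 2 arrays with disagreeing probes, the counts were 101 for A/J day 3, 1361 for AcB60 day 7, 205 and 193 for day 7 against day 3 in A/J and AcB60, and 75 for the strains at day 3. Without the 4 doubted arrays, where the A/J day 7 group is 1 mouse assumed to vary like the other groups, they were 438, 2146 and 986 for A/J at days 3, 5 and 7, 676 and 1900 for AcB60 at days 3 and 7, 77 for A/J day 7 against day 3, 102, 67 and 22 for the strains uninfected, at day 3 and at day 7, and 1 for the interaction at day 3. Without the 2 arrays with acinar transcripts, A/J day 3 had 0 (844 at an unadjusted p under 0.05 by limma) and the strains at day 7 had 17. Without the array lacking a response, A/J day 3 had 196, AcB60 day 3 had 220, AcB60 day 7 against day 3 had 21, and the interactions had 1 at day 3 and 2 at day 7.

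Camera with an estimated correlation called 8 lists and fry 75, in place of 153. The 11 list tests in which camera's direction, set against all other named genes, turned are given with their medians, which can keep their sign. They were MHC class I in A/J day 7 against day 3 (median 0.10) and in the interaction at day 7 (−0.16) without the 4 doubted arrays, both from that 1 A/J day 7 mouse, and, in AcB60 day 7 against day 3 without the array lacking a response, MHC class I (0.0402) and cytokines (0.22). In the strains at day 3, cytokines (0.28), monocyte markers (0.22) and red pulp macrophage markers (−0.0083) turned both without the 4 doubted arrays and without the array lacking a response. The acinar list in the averaged contrast turned without the 2 arrays with acinar transcripts (0.0469), which is where those transcripts lay.

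With 1 array left out at a time, the counts ranged from 0 to 27 for A/J day 3, 553 to 899 for day 5 and 1058 to 2314 for day 7, and from 0 to 220 and 342 to 541 for AcB60 at days 3 and 7. Day 7 against day 3 ranged from 117 to 785 in A/J and 21 to 133 in AcB60. The strains ranged from 27 to 96 uninfected, 25 to 40 at day 3, 20 to 385 at day 7 and 124 to 227 averaged, the interactions from 0 to 1 and 1 to 22, and the list calls from 137 to 167. The correlation between the strains' responses ranged from 0.424 to 0.736 at day 3 and 0.494 to 0.727 at day 7.

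The replicate number as a block gave 48, 1247, 2038, 0 and 844 genes for the infection comparisons in A/J at days 3, 5 and 7 and AcB60 at days 3 and 7, 394 and 93 for day 7 against day 3, 49, 46, 67 and 174 for the strains and 0 and 1 for the interactions, and moved no count by over 1.5 times. It ended the calls of 3 named genes, Vwf between the uninfected strains and Cxcl13 and Rsad2 in the averaged contrast. Of 63 same-numbered pairs of mice, 24 had deviations correlated over 0.1 (median 0.0519, from −0.356 to 0.762), so not every pair was correlated and the numbers were not used as pairs. By exact one-sided permutation of the numbers within groups, 12 of 21 arrays lay closest to their own number against a mean of 7 (p = 0.0709). The mean correlation was 0.0600 against 0.00254 (p = 0.0472 by the same permutation), so a shared structure between same-numbered mice stays open. The authors' processed values were not run, being identical to the unnormalized ones, and no slide block was run because the files name no slides.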

Other observations

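In A/J at day 7, some lists that did not pass as a whole held members that changed past limma's test. Of 21 stromal, matrix and endothelial genes 7 rose and 2 fell (median 0.72, adjusted p = 0.135), with the collagens Col1a1 up by 1.63 ± 0.53 and Col3a1 by 1.53 ± 0.39 while the scavenger receptor of sinusoidal endothelium Stab2 fell by 1.53 ± 0.45. Of 14 iron handling genes 2 rose and 1 fell (median 0.18, adjusted p = 0.929). The transferrin receptor Tfrc fell by 2.46 ± 0.77, while the ferroxidase Cp rose by 1.54 ± 0.41 and Slc11a1, the phagosomal metal transporter, by 1.47 ± 0.48. Of the 4 adipose markers measured, Lpl, lipoprotein lipase, rose by 1.85 ± 0.37 (list adjusted p = 0.584). Among T cell markers 3 of 19 rose (median 0.63, adjusted p = 0.110), with Zap70 up by 1.95 ± 0.34. Among NK and cytotoxic genes 3 of 13 rose (median 0.42, adjusted p = 0.281), with Klrg1 up by 1.96 ± 0.55 and Nkg7 by 1.55 ± 0.36. Among plasma cell markers Fkbp11 rose by 1.97 ± 0.42 and Mzb1 fell by 1.55 ± 0.29 (adjusted p = 0.263 for the list). With 1 array left out some of these gene calls ended. Those of Col1a1 and Slc11a1 ended without any 1 of the 6 arrays (adjusted p up to 0.128 and 0.121, without A/J uninfected replicates 2 and 1). Those of Stab2 (up to 0.0877) and Tfrc (up to 0.166) ended without each A/J uninfected mouse, and without A/J day 7 replicates 2 or 3 for Stab2 and replicate 1 for Tfrc, which then had −1.47. That of Col3a1 ended without A/J uninfected replicate 2 or A/J day 7 replicate 1 (up to 0.0606), that of Cp without A/J uninfected replicates 2 or 3 (up to 0.0780), and that of Klrg1 without A/J uninfected replicates 1 or 3 or A/J day 7 replicate 3 (up to 0.0744).

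Genes that differed between the strains in the averaged contrast lay next to each other along the chromosomes more often than shuffled calls. Of 10102 genes with a known order, 157 were called, and 7 pairs were direct neighbours against a mean of 2.42 in one-sided permutations (p = 0.0108). With a minimum change of 1 log2 unit this was lost, with 2 pairs (p = 0.214 by permutation). Both pairs, Prtn3 with Elane and S100a8 with S100a9, belong to the neutrophil list, which was lower in AcB60 as a whole. Shuffling calls over genes does not allow for neighbours that change together, so the excess need not come from chromosome segments. Within 10 tested genes of each other lay 61 pairs against 24.0 (p = 1e-05, the smallest the permutations can give). On chromosome 13, 12 of 351 genes were called, including Il6st, Esm1, Pelo and Emb. The excess on chromosome 2, the largest of any chromosome, had p = 8e-05 by permutation. The pairs within 10 genes and the chromosome excess were tested after the calls were seen.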
